A study of Bos taurus with 28 samples.

How the data were processed

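The samples were mammary biopsies of 28 cows of the Holstein-Friesian dairy breed, in the middle of lactation, and RNA of each cow was hybridised to its own Affymetrix Bovine Genome Array, a 1-colour array of short oligonucleotide probe sets. The groups were the DGAT1 genotypes given in the labels: 11 AA cows (alanine on both alleles), 13 KA cows and 4 KK cows (lysine on both alleles). The cows are separate animals, so the spread between arrays holds both biological and technical variation.

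The deposited values are log2 values per probe set. Per the labels' protocols, the authors processed the arrays with Bioconductor 2.7 in R 2.13. Per the submitters' processing notes, RMA and GCRMA were used, and which of them gave these values is not given in the sources used here. The table held 24128 probe sets with no missing value. The values lie around 0, so 1 baseline per probe set had been subtracted, a step that no source used here describes. The median over the 28 arrays was exactly 0 (tolerance 1e-06) for only 3.15% of probe sets, so the baseline was not the median of these arrays. In 29.0% of probe sets the values held an exact 0 or had a pair of equal size next to 0 (tolerance 2e-06), the share that a median over about 52.0 arrays would give. Absolute levels are therefore lost, values of different probe sets cannot be set against each other, and signal over background is unknown. Base 2 was checked from the rounding steps of the values: in 7 probe sets the range would put the top above 11.1, the natural log of the largest 16-bit signal.

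The 112 control probe sets were left out, which left 24016 to test. The planned choice of the probe set with the highest mean for each gene, and the planned filter on the dimmer probe sets, could not be made on values without levels. A coarse level class was read instead from the rounding steps: 4188 probe sets were bright, 13750 intermediate and 6078 dim. Each gene was represented by its probe set of the brightest class, then by the plainest probe set type, then by identifier. The platform annotation gave 1 gene symbol for 13292 tested probe sets, several for 86 and none for 10638. Symbols were updated through gene identifiers to the RefSeq table of assembly ARS-UCD2.0, which held 13263 of the 13292. The result was 9155 genes. No coordinates are given, since the build behind the probe sets is not named.

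Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over probe sets and a threshold of 0.05. One model with a mean per genotype gave KK minus AA, KA minus AA, KK minus KA, the departure of KA from the midpoint of AA and KK, and the F test over genotypes. A second model gave the slope per K allele, counted as 0, 1 and 2. No covariate entered these models. DGAT1 was also compared with two-sided permutation tests of the difference in mean, exact where a group had under 10 arrays and with 100000 resamples otherwise. Gene lists, 29 in all, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A permutation test of each list's mean over the arrays was added after the data had been seen. The correlation of KK minus AA with KA minus AA was set beside simulated unchanged groups and beside 100 splits of the AA arrays.

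The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule took up to 12 rises and 12 falls past the threshold from probe sets with 1 symbol. Where fewer than 10 genes passed, it took those and then the genes with the smallest p until 10 were reached, given as values only. It always took DGAT1, up to 10 of its neighbours with an unadjusted slope p under 0.05, and of each other list described at most 4 members with the smallest p.

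The scripts were tested on simulated arrays with the real groups and spread and with 200 changed probe sets among 24016. For KK minus AA, 32.0% of changes of 0.5 log2 and 90.0% of changes of 1 log2 were recovered. For KA minus AA the shares were 68.5% and 93.5%, and for the slope per K allele 88.0% and 98.0%. With no change simulated, 0 probe sets were called in each comparison. The simulated probe sets were independent of each other, which real ones are not.

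Alternatives were quantile normalization, centring of each array, leaving out dim probe sets, an intensity trend with robust variances, array weights, array number, the 3′ minus 5′ difference of the actin and GAPDH controls, stromal and immune scores, a threshold of 0.10, only the 2 groups compared, the mean over a gene's probe sets, lists without genes that stand in several, and leaving out each array in turn. Array numbers come from the sample titles, and whether they mark hybridisation order or batches is not given in the sources used here. Leaving out the arrays AA 2 and AA 9, blocking on the lower and upper array numbers, combining array weights with covariates, and testing within the lower or upper numbers were chosen after seeing the data. Milk yield and milk composition of single cows were not used here.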

Results

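Messenger RNA was measured in mammary biopsies of 28 lactating Holstein-Friesian cows that differed in DGAT1, the gene for an enzyme that catalyses the last step of triacylglycerol synthesis. The genotype was AA in 11 cows, KA in 13 and KK in 4, where K stands for lysine and A for alanine at the variable residue. The comparisons ask which genes differ in expression with this genotype. Each cow had 1 array, and the number of arrays limits the precision, above all for KK. All values are log2 differences from a baseline per probe set, so only differences between cows can be read.

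A pair of AA arrays, AA 2 and AA 9, stood apart from the other 26. The SD over probe sets was 0.86 in AA 2 and 0.78 in AA 9, against 0.21 to 0.35 in the others. These 2 arrays had 4807 and 3699 probe sets beyond 2-fold of the baseline, against 62 to 449 elsewhere, and they correlated with each other at r = 0.748 across probe sets, which are not independent replicates. The next highest pair of arrays reached 0.540. Milk fat globule genes averaged -1.88 in AA 2 and -2.23 in AA 9, against -0.27 to 0.27 in the other arrays, and fibroblast and matrix markers 0.83 and 1.27, against -0.45 to 0.40. The genotypes were also spread unevenly over the array numbers. Numbers 29 to 42 held 8 AA, 2 KA and 4 KK arrays, and numbers 43 to 56 held 3 AA, 11 KA and 0 KK arrays.

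**Figure D1:**
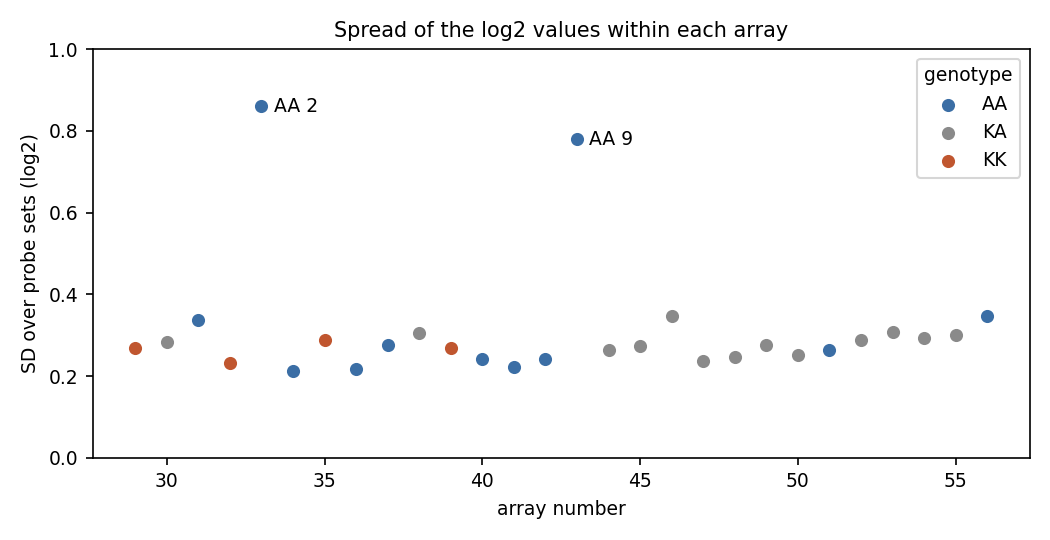
SD of the log2 values over the tested probe sets (vertical axis) against array number (horizontal axis), 1 point per cow, coloured by genotype. AA 2 at 0.86 and AA 9 at 0.78 lie above the other arrays, which range from 0.21 to 0.35.

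**Figure D2:**
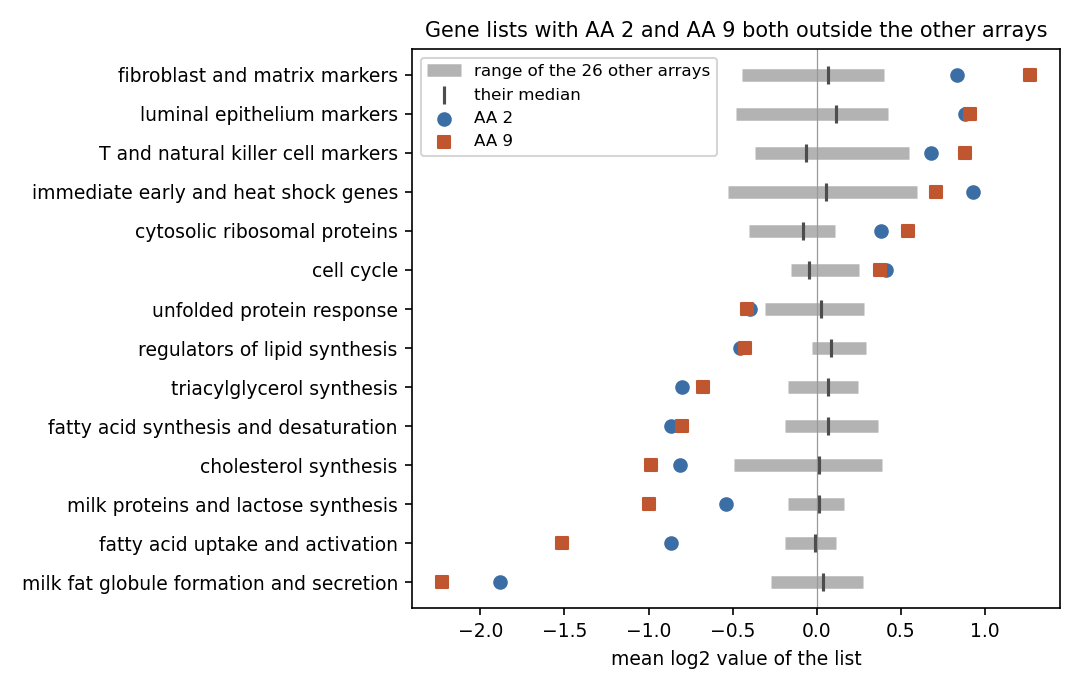
Mean log2 value (horizontal axis) of each gene list in which AA 2 (circles) and AA 9 (squares) both lay outside the other arrays; grey bars are the range of the 26 other arrays and ticks their median. Milk fat globule genes lie at -1.88 and -2.23 and fibroblast and matrix markers at 0.83 and 1.27.

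The DGAT1 signal was higher in cows with the K allele, and whether the variable site lies under the probes was not tested. The DGAT1 log2 value was -0.02 ± 0.34 (SD, n = 11) in AA, 0.34 ± 0.23 (SD, n = 13) in KA and 0.55 ± 0.34 (SD, n = 4) in KK. KK exceeded AA by 0.57 log2, or 1.49-fold (exact two-sided permutation p = 0.0103, adjusted over the 3 pairs 0.0154), and 4 of 4 KK cows lay above the AA mean. KA exceeded AA by 0.37 log2, or 1.29-fold (two-sided permutation p = 0.00374, adjusted 0.0112), with 12 of 13 KA cows above the AA mean. KK and KA differed by 0.20 log2, which did not pass (exact permutation p = 0.183), and by 0.11 without KK 3 and 0.37 without KK 1. The slope was 0.31 log2 per K allele (SE 0.08), ranked 7 by p among the 24016 probe sets, and it did not pass the adjustment over probe sets (limma adjusted p = 0.526).

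Within array numbers 29 to 42, KK exceeded AA by 0.70 log2 in DGAT1 (exact permutation p = 0.00606, n = 4 and 8). KA exceeded AA by 0.25 there (exact permutation p = 0.267, n = 2 and 8, and 0.17 without AA 2) and by 0.06 within numbers 43 to 56 (exact permutation p = 0.657, n = 11 and 3), so the difference between KA and AA did not hold within either range. With the lower and upper numbers as a block the DGAT1 slope was 0.30 per K allele.

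**Figure D3:**
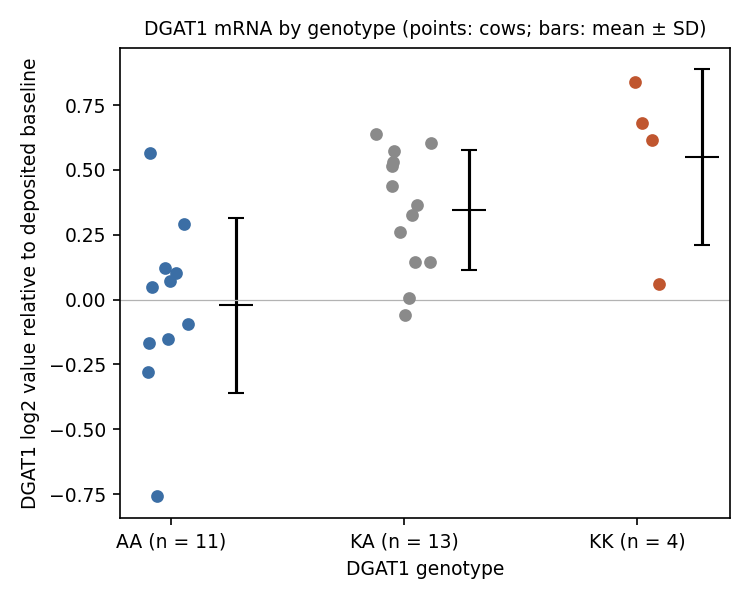
DGAT1 log2 value relative to the deposited baseline (vertical axis) by genotype (horizontal axis), 1 point per cow, with the mean and SD of each group as bars. Group means are -0.02 in AA, 0.34 in KA and 0.55 in KK, and the groups overlap.

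Per K allele, camera with a preset correlation between genes called lists of lipid and cholesterol metabolism upward. It called lists of stromal and contractile cells downward. With an estimated correlation no list passed, and no single probe set passed in limma. Cholesterol synthesis had positive slopes in 15 of 15 measured genes, with a median of 0.18 log2 per K allele (camera adjusted p = 5.96e-08, and adjusted p = 0.488 with an estimated correlation). Its members with the smallest p were HMGCS1, which makes the precursor of mevalonate, at 0.44 (SE 0.15), TM7SF2 at 0.35 (SE 0.13), NSDHL at 0.31 (SE 0.11) and DHCR7, which makes cholesterol in the last step of the pathway, at 0.30 (SE 0.12). Adjusted over the list alone, 8 of the 15 passed, all upward, and 0 passed over all genes. At an unadjusted limma p under 0.05 there were 8 of the 15 with all arrays and 1 without AA 2 and AA 9. With the lower and upper array numbers as a block the slope of the list mean was 0.22, as without it. KA minus AA was 0.21 within numbers 29 to 42 and 0.54 within 43 to 56, but 0.12 without AA 2 and 0.29 without AA 9. The 0.12 rests on 2 KA arrays. The AA arrays behind the 0.29 are AA 10 at -0.49, the lowest array besides AA 2 and AA 9, and AA 11 at 0.01. In AA 2 and AA 9 the mean of this list was -0.81 and -0.99, against -0.49 to 0.39 in the other arrays.

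Fibroblast and matrix markers had negative slopes in 17 of 20 genes, with a median of -0.27 (camera adjusted p = 6.46e-06, and adjusted p = 0.488 with an estimated correlation). OGN, a small matrix proteoglycan, had a slope of -0.52 (SE 0.14), the fibrillar collagen COL1A2 -0.41 (SE 0.16) and the proteoglycan DCN -0.38 (SE 0.14). Adjusted over the list alone 1 passed, OGN, and 0 passed over all genes. At an unadjusted limma p under 0.05 there were 11 of the 20, all downward, and 1 without AA 2 and AA 9. Myoepithelium and smooth muscle markers had negative slopes in 13 of 13 genes, with a median of -0.22 (camera adjusted p = 1.05e-04, and adjusted p = 0.488 with an estimated correlation). Among them the basal keratin KRT5 had a slope of -0.42 (SE 0.13) and the smooth muscle myosin MYH11 -0.30 (SE 0.11), and adjusted over the list alone 1 passed, KRT5. Cytosolic ribosomal proteins had negative slopes in 61 of 65 genes, with a median of -0.09 (camera adjusted p = 2.87e-08, and adjusted p = 0.587 with an estimated correlation), and 0 passed adjusted over the list alone. The ribosomal list averaged 0.38 in AA 2 and 0.54 in AA 9, above 0.11 in the highest other array. With the array number block the slopes of the list means were -0.23 for fibroblast, -0.21 for myoepithelium and -0.08 for ribosomal genes. KA minus AA within numbers 29 to 42 and 43 to 56 was 0.01 and -0.50 for myoepithelium, and -0.19 and -0.47 for fibroblast markers. Without AA 2 in the lower and AA 9 in the upper numbers these were 0.07 and -0.30, and -0.10 and -0.07.

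The other lists that passed per K allele all shifted upward. Milk fat globule formation and secretion had positive slopes in 11 of 14 genes (median 0.28, camera adjusted p = 0.00986, and adjusted p = 0.582 with an estimated correlation). Its members included CIDEA, a lipid droplet protein that lay below -2 only in AA 2 and AA 9, at 0.90 (SE 0.38) and PLIN2, a coat protein of lipid droplets, at 0.41 (SE 0.19), with BSCL2 at -0.33 (SE 0.15). Fatty acid uptake and activation had a median of 0.20 in 15 genes (camera adjusted p = 0.0474, and adjusted p = 0.518 with an estimated correlation), with the acetate-activating enzymes ACSS2 at 0.60 (SE 0.24) and ACSS1 at 0.40 (SE 0.15). The median of this list was 0.07 after quantile normalization and 0.05 without AA 2 and AA 9. Fatty acid synthesis and desaturation had a median of 0.09 in 17 genes (camera adjusted p = 0.0302, and adjusted p = 0.582 with an estimated correlation). Regulators of lipid synthesis had positive slopes in 18 of 20 genes (median 0.05, camera adjusted p = 0.0279, and adjusted p = 0.582 with an estimated correlation), led by INSIG1 at 0.54 (SE 0.20) and the transcription factor SREBF1 at 0.35 (SE 0.13). The unfolded protein response (median 0.08, camera adjusted p = 0.0279, and adjusted p = 0.587 with an estimated correlation), milk proteins and lactose synthesis (median 0.11, camera adjusted p = 0.0398, and adjusted p = 0.669 with an estimated correlation) and triacylglycerol synthesis (median 0.06, camera adjusted p = 0.0398, and adjusted p = 0.582 with an estimated correlation) followed. In triacylglycerol synthesis 1 gene passed adjusted over the list alone, DGAT1 itself. AA 2 and AA 9 lay below the other 26 arrays in each of these 7 lists.

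In all, 11 of 29 lists passed per K allele, 8 upward and 3 downward. With an estimated correlation 0 passed, the smallest adjusted p being 0.488, and permutation of the genotypes over the arrays gave 0 lists past the threshold after adjustment, with 5 at an unadjusted p under 0.05. With fry 0 passed (smallest adjusted p = 0.167), with 4 at an unadjusted p under 0.05. Without AA 2 and AA 9, 6 lists passed camera at the preset correlation, of which 2, cholesterol synthesis and fibroblast markers, had an unadjusted permutation p under 0.05, and with an estimated correlation 0 passed (smallest adjusted p = 0.294). Cholesterol synthesis (median slope 0.13), fibroblast and matrix markers (-0.13), myoepithelium and smooth muscle markers (-0.13) and ribosomal proteins (-0.02) were among them. Myeloid cell markers (0.08) and the respiratory chain (0.03) newly passed. The milk and the other lipid lists did not pass, with medians of 0.05 for fatty acid uptake, 0.04 for milk fat globule formation and 0.03 for fatty acid synthesis. Lipid regulators had 0.02, milk proteins 0.005 and triacylglycerol synthesis -0.0035. The unfolded protein response (0.03) did not pass either. Without KK 4 as well, the myeloid list did not pass (0.04) and the milk fat globule list did (0.08). Leaving out AA 9 alone left 4 lists, and leaving out KK 3 left 7.

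**Figure D4:**
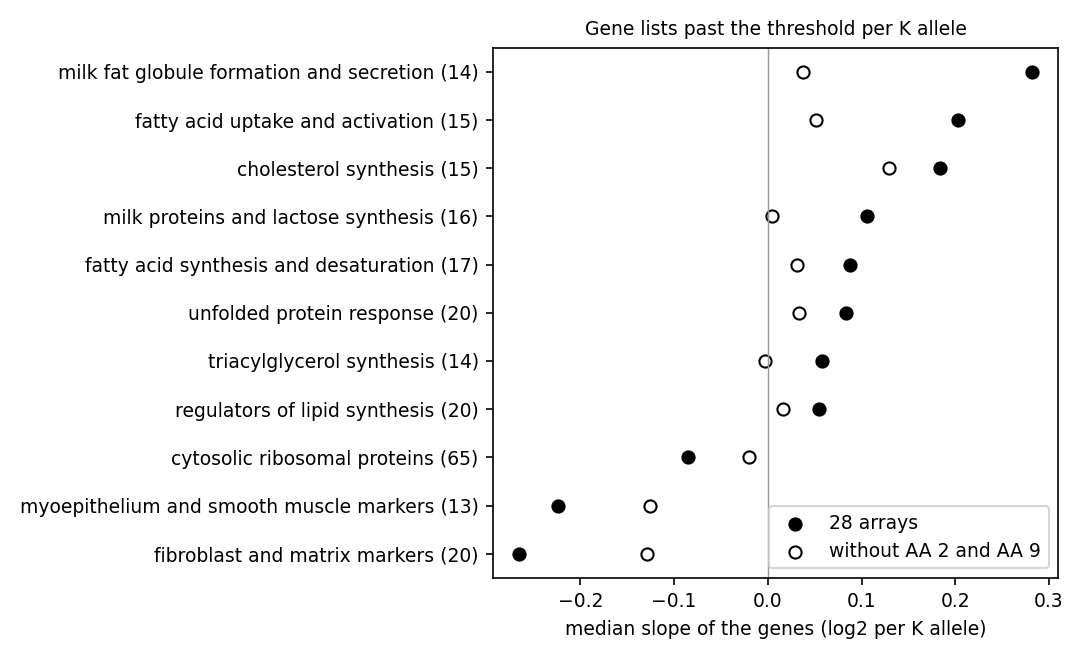
Median slope per K allele in log2 (horizontal axis) of each gene list that passed camera in 28 arrays, with the number of measured genes in brackets; filled points use 28 arrays and open points leave out AA 2 and AA 9. Milk fat globule genes move from 0.28 to 0.04 and cholesterol synthesis from 0.18 to 0.13.

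No probe set passed per K allele (limma, smallest adjusted p = 0.526). At an unadjusted p under 0.05 there were 2199 of 24016, against 1201 expected on average for unchanged probe sets, and 784 without AA 2 and AA 9. The genes with the smallest p, which are values and not calls, were PI16 at -0.36 per K allele (SE 0.08), LOC404051 at -0.18 (SE 0.04), MFSD10 at 0.19 (SE 0.05), PPIC at -0.31 (SE 0.07), P3H2 at -0.23 (SE 0.06), AMIGO2 at -0.30 (SE 0.08), STK3 at -0.20 (SE 0.05), TOR1AIP2 at 0.17 (SE 0.05) and SCG5 at -0.35 (SE 0.09), besides DGAT1. Other probe sets had slopes of 0.08 and 0.08 in LOC404051, 0.02 in STK3 and -0.07 in TOR1AIP2, against the direction of the named one, and of -0.05 in PPIC and -0.09 in AMIGO2.

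Between KK and AA cows, cholesterol synthesis and the stromal and contractile lists shifted in camera with a preset correlation between genes. With an estimated correlation none passed. Cholesterol synthesis lay higher in KK for 15 of 15 genes (median 0.36 log2, camera adjusted p = 2.24e-08, and adjusted p = 0.209 with an estimated correlation), with HMGCS1 at 0.81 (SE 0.32) and MSMO1, a sterol demethylating enzyme, at 0.36 (SE 0.16). Fibroblast and matrix markers lay lower for 17 of 20 genes (median -0.47, camera adjusted p = 1.39e-07, and adjusted p = 0.209 with an estimated correlation), with OGN at -1.08 (SE 0.31) and the matrix protein POSTN at -0.93 (SE 0.40). Myoepithelium and smooth muscle markers lay lower for 13 of 13 genes (median -0.48, camera adjusted p = 9.27e-07, and adjusted p = 0.209 with an estimated correlation), with KRT5 at -0.68 (SE 0.27) and the contractile protein CNN1 at -0.58 (SE 0.23). Adjusted over the list alone, OGN passed in the fibroblast list and 0 genes passed in the other 2 lists.

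Ribosomal proteins lay lower in KK for 61 of 65 genes (median -0.14, camera adjusted p = 1.39e-07, and adjusted p = 0.616 with an estimated correlation). The unfolded protein response (median 0.17, camera adjusted p = 0.0222, and adjusted p = 0.616 with an estimated correlation), fatty acid uptake and activation (median 0.33, camera adjusted p = 0.0306, and adjusted p = 0.325 with an estimated correlation) and milk fat globule formation (median 0.41, camera adjusted p = 0.0306, and adjusted p = 0.616 with an estimated correlation) lay higher. In all 7 lists passed, 4 upward and 3 downward, while permutation of the arrays gave 0 even at an unadjusted p under 0.05, and fry 0 after adjustment (smallest adjusted p = 0.255) and 3 at an unadjusted p under 0.05. Without AA 2 and AA 9, 9 lists passed camera at the preset correlation, 0 of them at an unadjusted permutation p under 0.05 and 0 with an estimated correlation (smallest adjusted p = 0.233), with smaller medians for cholesterol synthesis (0.27), fibroblast (-0.27) and myoepithelium markers (-0.31), fatty acid uptake (0.14) and ribosomal proteins (-0.04). The milk fat globule list and the unfolded protein response no longer passed, and T and natural killer cell (0.14), B and plasma cell (0.22) and myeloid markers (0.14) and the respiratory chain (0.08) newly passed, all upward. Without KK 4 as well, the T cell (0.07), B cell (-0.04) and myeloid lists (-0.01) and fatty acid uptake (0.13) did not pass, so the immune shift rests on 1 cow. With the array number block 4 lists passed, and within numbers 29 to 42 KK minus AA was 0.29 for cholesterol synthesis, -0.36 for fibroblast and -0.32 for myoepithelium markers, and 0.19, -0.27 and -0.26 without AA 2. The other lists shrank more. Ribosomal proteins went from -0.06 to 0.003 without AA 2, milk fat globule formation from 0.29 to 0.065 and fatty acid uptake from 0.19 to 0.09. The unfolded protein response went from 0.12 to 0.08.

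No probe set passed between KK and AA (limma, smallest adjusted p = 0.909). At an unadjusted p under 0.05 there were 842, against 1201 expected on average for unchanged probe sets, and 662 without AA 2 and AA 9. The smallest p belonged to PPIC, a peptidyl-prolyl isomerase, at -0.72 (SE 0.15), PI16 at -0.73 (SE 0.18), LOC404051 at -0.37 (SE 0.09), ERAP2, an aminopeptidase that trims antigenic peptides, at 0.95 (SE 0.23), P3H2, a collagen prolyl hydroxylase, at -0.50 (SE 0.12), MFSD10 at 0.35 (SE 0.10), RBL2 at 0.41 (SE 0.12), RASL11B at 0.77 (SE 0.22), LTB4R at 0.28 (SE 0.08) and ARSK at -1.06 (SE 0.31). Each had 4 of 4 KK cows on the same side of the AA mean, but they were picked by p in these same arrays, so this adds no support. The other probe set of PPIC differed by only -0.09, those of RBL2 by -0.18 and 0.02, those of LOC404051 by 0.13 and 0.05, and that of RASL11B by 0.36. Without KK 1 the difference in ARSK was -0.65.

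Between KA and AA cows, lists of lipid genes shifted upward and lists of T cell and ribosomal genes downward in camera with a preset correlation between genes, and with an estimated correlation none passed. Cholesterol synthesis lay higher for 15 of 15 genes (median 0.31, camera adjusted p = 2.82e-04, and adjusted p = 0.626 with an estimated correlation), with LSS, which forms lanosterol, at 0.47 (SE 0.16) and TM7SF2 at 0.51 (SE 0.19). Regulators of lipid synthesis lay higher for 18 of 20 (median 0.16, camera adjusted p = 0.00341, and adjusted p = 0.626 with an estimated correlation), with the sterol receptors NR1H3 at 0.24 (SE 0.09) and NR1H2 at 0.24 (SE 0.10). It was the only list of 29 past the threshold by permutation of the arrays after adjustment (adjusted permutation p = 0.00348, KA and AA cows only), and without AA 2 and AA 9 it did not pass that adjustment (unadjusted permutation p = 0.00216). With fry 0 lists passed (smallest adjusted p = 0.0597), with 6 at an unadjusted p under 0.05. T and natural killer cell markers lay lower for 17 of 19 genes (median -0.29, camera adjusted p = 0.00341, and adjusted p = 0.626 with an estimated correlation), with the T cell receptor components CD3G at -0.71 (SE 0.24) and CD3E at -0.33 (SE 0.13). These 3 lists and the ribosomal proteins (59 of 65 lower, median -0.13, camera adjusted p = 2.64e-06, and adjusted p = 0.626 with an estimated correlation) passed camera also without AA 2 and AA 9, with medians of 0.11 for cholesterol synthesis, 0.10 for the lipid regulators, -0.07 for the T cell list and -0.03 for ribosomal proteins. Within array numbers 29 to 42 and 43 to 56, KA minus AA was 0.08 and 0.23 for the lipid regulators and -0.15 and -0.38 for the T cell list, and it turned for ribosomal proteins, at 0.06 and -0.35. Without AA 2 in the lower and AA 9 in the upper numbers these were 0.02 and 0.07, -0.06 and -0.06, and 0.12 and -0.20. The T cell list averaged 0.68 in AA 2 and 0.88 in AA 9, above 0.55 in the highest other array.

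Another 5 lists passed between KA and AA with 28 arrays and not without AA 2 and AA 9, each with adjusted p = 0.626 with an estimated correlation. Milk fat globule formation had a median of 0.52, fibroblast and matrix markers -0.34, the major histocompatibility complex -0.36, milk proteins and lactose synthesis 0.17 and fatty acid synthesis 0.15. In fatty acid synthesis 2 genes passed adjusted over the list alone, AACS, which activates acetoacetate, at 0.53 (SE 0.15) and ACACA, the rate-limiting enzyme of the pathway, at 1.01 (SE 0.32). In the histocompatibility list 19 of 22 genes lay lower in KA and 3 higher. Its members with the smallest p were BOLA-DQA5 at 1.55 (SE 0.55), TAP2 at -0.51 (SE 0.19), BOLA-N at -1.71 (SE 0.67) and BOLA-DQB at 0.95 (SE 0.37). Adjusted over the list alone 0 passed. The histocompatibility list differed by -0.77 within numbers 43 to 56, where AA 9 is 1 of 3 AA arrays (-0.33 without it), and by 0.00 within 29 to 42. Leaving out AA 9 alone left 5 lists.

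No probe set passed between KA and AA (limma, smallest adjusted p = 0.0602). At an unadjusted p under 0.05 there were 5247, against 1201 expected on average for unchanged probe sets, and 2281 without AA 2 and AA 9. Random splits of the arrays gave a median of 727 and at most 8730. Without AA 2 and AA 9 they gave a median of 946 and at most 2831. The smallest p belonged to BLTP3B at -0.77 (SE 0.14), the tyrosine kinase LYN at 0.54 (SE 0.11), MOCS1, an enzyme of molybdenum cofactor synthesis, at 0.76 (SE 0.15), AACS at 0.75 (SE 0.16), CYFIP1 at 0.43 (SE 0.09), PDHA1, a subunit of pyruvate dehydrogenase, at 0.93 (SE 0.20), AGPAT3, an acyltransferase of glycerolipid synthesis, at 0.33 (SE 0.07), CCDC86 at 0.44 (SE 0.10), the Wnt receptor FZD4 at 0.43 (SE 0.10) and KITLG, the ligand of the receptor KIT, at 0.53 (SE 0.12). FZD4 had the same direction in 12 of 13 KA cows and the others in 13 of 13, which adds no support, since p in these same arrays picked them. Other probe sets of AACS (0.53), MOCS1 (0.61) and CCDC86 (0.45) lay near these values, and those of LYN (-0.01 and 0.07), CYFIP1 (-0.26), PDHA1 (0.11, 0.04 and 0.46), AGPAT3 (0.05 and 0.07) and FZD4 (0.17) did not. Leaving out AA 1 raised the count from 0 to 525, and array weights raised it to 104.

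No probe set passed between KK and KA (limma, smallest adjusted p = 1), and 3 did with array weights. At an unadjusted p under 0.05 there were 681, against 1201 expected on average for unchanged probe sets, and 1459 without AA 2 and AA 9. These 2 arrays are in neither group and enter this comparison only through the spread that the model shares over genotypes. The 681 therefore do not show that KK and KA are alike. The smallest p belonged to BLTP3B at 0.89 (SE 0.20), ST8SIA4 at 0.58 (SE 0.14), RBM18 at -0.47 (SE 0.11), RGS1, a regulator of G protein signalling, at 1.75 (SE 0.42), CUX1 at 0.45 (SE 0.11), PPIC at -0.57 (SE 0.15), the lymphocyte receptor LY9 at 0.54 (SE 0.14), GCLM at -0.40 (SE 0.11), CCAR1 at 0.61 (SE 0.17) and LOC526041 at 0.47 (SE 0.13). Other probe sets of CUX1 had -0.11 and -0.45, those of RBM18 -0.06 and 0.08, and those of PPIC 0.00, LY9 -0.11 and CCAR1 0.27.

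BLTP3B was the only probe set that departed from additivity, with KA minus the midpoint of AA and KK at -0.83 log2 (SE 0.14, limma adjusted p = 0.0413). Its mean was 0.12 ± 0.46 (SD, n = 11) in AA, -0.65 ± 0.26 (SD, n = 13) in KA and 0.23 ± 0.30 (SD, n = 4) in KK. At an unadjusted p under 0.05 there were 2356 probe sets. The call depends on the arrays and the model. It was made without KK 1, AA 1, AA 3, AA 5, AA 7, KA 7 or KA 9, and none when any other single array was left out, with the lower and upper array numbers as a block, with a 3′ minus 5′ term or with an intensity trend. The F test over the 3 genotypes passed for 0 probe sets (limma, smallest adjusted p = 0.126), with 2879 at an unadjusted p under 0.05.

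Genes next to DGAT1 were not enriched among the genes with the smallest slope p, but so few genes had one that the test could hardly show enrichment. Of 33 measured neighbours from the fixed list, 0 had an unadjusted slope p under 0.01, against 117 of 9121 other genes (one-sided Fisher's exact test, p = 1), and the same held for 39 genes within 5 Mb by the order of genes on ARS-UCD2.0. The neighbours with an unadjusted p under 0.05 were VPS28 at -0.15 (SE 0.06), CYHR1 at 0.12 (SE 0.06), TONSL at 0.11 (SE 0.05) and GFUS at 0.32 (SE 0.15) per K allele, and 0 passed adjusted over the list alone. Of all probe sets 9.16% had an unadjusted slope p under 0.05. Without AA 2 the slope of GFUS was 0.18 and that of TONSL 0.07. As a list the neighbours did not shift (camera adjusted p = 0.382).

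Across probe sets, KK minus AA correlated with KA minus AA at r = 0.745, with both sharing the AA arrays. Simulated unchanged groups, which also shared the AA arrays, gave 0.378. Splitting the AA arrays into separate parts gave a median of 0.441 over 100 splits, from -0.22 to 0.646. These parts share no AA array, so the simulated value is no reference for them. With the genotypes permuted over the arrays the median was 0.455, and 14 of 100 permutations reached the observed correlation. The covariance was 0.0345 against 0.00966 in the simulation, and 4 of 100 permutations reached it. Without AA 2 and AA 9 the correlation was 0.371 and the covariance 0.00712, both below the values simulated for 28 arrays. Neither comparison had a call, so there was no overlap to count.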

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

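The permutation tests of gene lists, the splits of the 26 arrays without AA 2 and AA 9, the degradation and epithelium tests of those arrays and the cholesterol test without them were chosen only after the result was seen. Among 57 sets of 4 KK values, 6 held an array far from the other 3, where chance gives about 2.85. Myoepithelium and smooth muscle markers averaged 0.34 in KK 3 against -0.37 to -0.35 in the other KK arrays (gap over range 0.971). B and plasma cell markers averaged 1.16 in KK 4 (0.891), and myeloid cell markers 1.06 in KK 4 against -0.11 to 0.01 (0.899). Hormone and growth factor signalling genes averaged 0.12 in KK 3 (0.841), and phospholipid and sphingolipid synthesis genes 0.09 in KK 3 (0.932). GCLM lay at -0.38 in KK 2 against -0.16 to -0.14 (0.896).

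AA 2 and AA 9 stood apart from the other 26 arrays, with milk fat, fatty acid and milk protein genes low and fibroblast, luminal, T cell and ribosomal genes high. RNA degradation could be part of the account for AA 2, whose 3′ minus 5′ difference of 0.597 lay above the highest other array at 0.34, and is argued against for AA 9 at -0.436, below the lowest other at -0.32. Weak hybridisation is argued against as the whole account, since bright probe sets lay above dim ones in both arrays, by up to 0.333. It stays open as a part in AA 9, whose hybridisation spikes were the lowest of 28 arrays at -0.93 (AA 2 -0.43). Weak labelling stays open too, with poly-A spikes at -1.25 in AA 2, the lowest, and -0.70 in AA 9. AA 11, with poly-A spikes at -0.94, had an SD over probe sets of 0.35, against 0.86 in AA 2 and 0.78 in AA 9. Yet among the other 26 arrays AA 11 had the most probe sets beyond 2-fold (449) and the highest 3′ minus 5′ difference (0.34). Among the values of 6 non-epithelial lists in both arrays, 1 lay below every other array. It was endothelium at -0.34 in AA 2, close to the lowest other array at -0.26. Fibroblast markers at 0.83 and T cell markers at 0.68 in AA 2 lay above the 26 other arrays, as a lower share of epithelium would give. These lists therefore cannot decide on a lower share of epithelium. Luminal markers argue against it as the whole account, at 0.88 in AA 2 and 0.91 in AA 9, above 0.43 in the highest other array. A change in cell composition stays open in both arrays, also for AA 9, whose endothelium markers lay at 0.30. Health and lactation state stay open too and were not tested.

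DGAT1 rose with the number of K alleles in the permutation tests. AA 2 and AA 9 are argued against as the cause, since the slope without them was 0.274 (permutation p = 0.00105, against 0.31 with them). Stromal and immune content is argued against too, at 0.376 (permutation p = 2e-05) with both scores. With array number the slope was 0.325 (permutation p = 1e-05, the smallest that the resamples can give). That term cannot decide on array order. The median array number was 40 in AA, 48 in KA and 33.5 in KK, so K alleles did not rise along the numbers. KK minus AA held within numbers 29 to 42. KA minus AA passed no test within either range of array numbers, so array order stays open for KA. Whether the variable site lies under the DGAT1 probes was not tested, so a hybridisation difference between alleles stays open beside a difference in mRNA level.

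The cholesterol synthesis list had a higher mean per K allele, with a slope of 0.22. AA 2 and AA 9 may account for part of it, since without them the slope was 0.122 (permutation p = 0.0292). Stromal and immune content (0.204) is argued against. Array order stays open: the slope with array number was 0.217, but K alleles did not rise along the numbers, so this term could hardly change it. Chance cannot be excluded: the permutation p was 0.00695, and the condition set beforehand, a p under 0.05, was wrong because the list was singled out among 29 (adjusted permutation p = 0.167).

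Where limma made 0 calls, 100 of 100 splits of the arrays into groups of the same sizes gave as many, but any split reaches a count of 0, so the splits say nothing there. Real and highest other counts were 0 and 3 for KK against AA, 0 and 2911 for KA against AA, 0 and 7 for KK against KA, 0 and 674 per K allele, and 0 and 1 for the F test, with 842, 5247, 681, 2199 and 2879 at an unadjusted p under 0.05. The odds ratio near DGAT1 was 0, the highest other 28.5, and 100 splits were as large, which again says nothing. The highest splits for KA against AA put AA 2 and AA 9 both in AA, which points to a structure of the arrays. For departures 2 of 100 splits gave 1 call or more (highest other 1). This argues against chance only among splits that ignore array number, and it was not adjusted for the several counts tested by splits. With the array number block, the 3′ minus 5′ term or the intensity trend the departures numbered 0, and most single arrays left out ended the call, so array order and quality stay open. Lists shifted as often in 19 of 100 splits per K allele (11, highest other 18), 46 for KK against AA (7, highest other 19) and 37 for KA against AA (9, highest other 16), so chance cannot be excluded. Of the splits other than the real one, 97, 95 and 95 had at least 1 list that passed.

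Between KA and AA, 3 of 100 splits had as many probe sets at an unadjusted p under 0.05 (5247, highest other 8730). With array weights 4 of 100 had as many calls (104, highest other 875). Both shares argue against chance only among splits that ignore array number, and they were not adjusted for the several counts tested by splits. Genotype and array number go together, and the highest split of each count put AA 2 and AA 9 both in AA, so array order and these arrays stay open. Without AA 2 and AA 9, 7 of 100 splits of the 26 arrays had as many (2281, highest other 2831), so chance cannot be excluded there.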

How the results depend on the processing

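Leaving out AA 2 and AA 9, also together with KK 4, the block on lower and upper array numbers, array weights together with another term or used for gene lists, and fits within the lower or upper numbers were chosen after the results had been seen. The DGAT1 slope kept its direction and an unadjusted limma p under 0.05 in 39 of 39 alternatives, from 0.26 to 0.38 per K allele (largest p = 0.00217). A fit within numbers 43 to 56 is not among these. There KA exceeded AA by only 0.06 in DGAT1 (exact permutation p = 0.657). Probe sets called per K allele stayed at 0 in limma under the alternatives run for that slope. Fits within numbers 43 to 56 are not among them. No KK array lies in that range, so a slope there would equal KA minus AA, which had calls, given below. Of 407 values of named genes under other settings, 387 kept their direction and side of the threshold, 20 newly passed and 0 turned.

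Probe sets called between KA and AA, 0 in the fit of all arrays, numbered 104 with array weights, 249 with weights and array number, 248 with weights and composition scores, 47 after quantile normalization, 12 at the threshold of 0.10, 5 with array number, 5 without dim probe sets, 3 with stromal and immune scores, 2181 within array numbers 43 to 56 and 6 there without AA 9. With weights and array number 1 passed between KK and AA. Between KK and KA, 3 passed with weights and 1 with weights and composition scores. Departures from additivity, 1 in the fit of all arrays, numbered 80 with weights, 19 with weights and array number, 22 with weights and composition scores, 20 after quantile normalization, 6 without AA 2 and AA 9, 2 with array number, and 0 with the 3′ minus 5′ term, the array number block or the intensity trend. The F test gave 19 with weights, 23 with weights and array number, 24 with weights and composition scores, 5 after quantile normalization and 1 with stromal and immune scores.

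Lists per K allele, 11 at the preset correlation, numbered 0 with an estimated correlation, 5 with weights, 5 with weights and array number, 6 without AA 2 and AA 9 and 7 after quantile normalization. Lists between KK and AA, 7 at the preset correlation, numbered 0 with an estimated correlation, 4 with the block and 11 with array number. Lists between KA and AA, 9 at the preset correlation, numbered 0 with an estimated correlation, 5 with weights and 4 without AA 2 and AA 9. The correlation of KK minus AA with KA minus AA fell from 0.745 to 0.512 after quantile normalization and 0.371 without AA 2 and AA 9. The odds ratio of genes near DGAT1, 0 with all arrays, was 7.67 without AA 2 and AA 9 (one-sided Fisher's exact p = 0.129).

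With each array left out in turn, calls between KA and AA ranged from 0 to 525, the highest without AA 1, with 5 without KK 3 or KA 5 and 1 without AA 7 or KA 9. Departures ranged from 0 to 1 and F test calls from 0 to 3, the highest without AA 1. Lists per K allele ranged from 4 without AA 9 to 12, with 7 without KK 3, and lists between KA and AA from 5 without AA 9 to 11. Apart from the arrays left out and the threshold, the cause was not tested. No paired analysis was possible because the replicate numbers name different cows and pair none of them. Signal over background is unknown in these values, so dim probe sets were left out by a coarse class read from rounding steps.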

Other observations

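The genes of the first 2 paragraphs were chosen after their values were seen, by their range over the arrays, and their tests and the fits with array weights and a further term were chosen only after the result was seen. BOLA-DQB1 and BOLA-DQA2, class II histocompatibility genes, spanned 8.03 and 7.88 log2 over the 28 arrays. Both lay below -2 in the same 6 arrays, KK 3, AA 4, AA 7, KA 3, KA 6 and KA 8, which hold all 3 genotypes, and their slopes per K allele had unadjusted limma p of 0.627 and 0.347. LOC783399 spanned 8.10 and LOC785756 7.35, with unadjusted slope p of 0.521 and 0.183.

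ALOX15, a lipoxygenase, and CIDEA, a lipid droplet protein, lay below -2 only in AA 2 and AA 9, with lowest values of -6.03 and -6.79. SPADH1 lay below -2 in the same pair of arrays, and CFI, a complement factor, lay above 2 only there, reaching 4.65. BOLA-N lay above 2 in AA 2, AA 6, AA 8, AA 9 and KK 4, and CHI3L1, a secreted glycoprotein, in AA 2, AA 9, KK 3, KA 2 and KA 9.

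Adjusted over the list alone, the B cell genes CD38 and MS4A1 passed per K allele, at 0.28 (SE 0.09) and 0.19 (SE 0.07), while 3 of 8 genes of that list had positive slopes and the list did not shift (camera adjusted p = 0.609). KK 4 was far above the other KK arrays in this list.

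With array weights 104 probe sets passed between KA and AA, 62 higher and 42 lower in KA. The weights of AA 2 and AA 9 were 0.10 and 0.15. Of the 104, 66 were also called with array number added, 94 with composition scores added and 41 after quantile normalization.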
